A study of Homo sapiens with 4 samples.

How the data were processed

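Messenger RNA was sequenced from 2 human colorectal cancer cell lines, HT29 and RKO, each as a wild-type culture and as a culture overexpressing ZCCHC7. Per the labels' protocols, RNA was extracted with Trizol, poly(A) RNA was selected on oligo-dT beads and fragmented, and paired-end libraries were sequenced on an Illumina NovaSeq instrument. The labels give 1 sample to each of the 4 groups, so no group has a replicate. How ZCCHC7 was overexpressed, whether the wild-type cells carried an empty vector and whether the libraries keep strand are not given in the sources used here. The extraction text in the labels speaks of adipose tissue, which is at odds with the cell lines named for the same samples.

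The authors deposited 1 table per line, with 60612 rows keyed by human Ensembl gene identifiers and, per the file headers, the FPKM of each of the 2 libraries (fragments scaled by transcript length and library total). The same tables hold the authors' fold change, which is the ratio of the 2 deposited FPKM values, its log2 value, and a p-value and q-value whose test is not given in the sources used here. In the deposited FPKM columns a value of 0.0001 stood in place of 0 and was read as 0. HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 are named without their roles, per the submitters' processing notes, and so is the mouse build mm8, which cannot be the build behind human gene identifiers. The human build and annotation release behind the values are therefore not given in the sources used here. Identifiers were matched to GENCODE release 29 on GRCh38 for gene position, gene type, exon overlap and transcript length and GC content, and 58394 of the 60612 rows (96.3%) matched.

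The FPKM columns summed to 355644 in HT29 wild type, 357994 in HT29 overexpression, 358677 in RKO wild type and 364728 in RKO overexpression. The number of reads per library is unknown. A value that recurred as a multiple or a part among 26 to 42 low genes per library, within 2e-06, stood at 0.175 to 0.190 FPKM. If it came from like transcripts in each library, the depths would lie within 1.09 times of each other. The value was sought only within a narrow range of low FPKM, so this is weak evidence of equal depth. Between 39390 and 40492 rows per library were listed at 0. Mitochondrially encoded genes held 36.0%, 39.6%, 36.1% and 32.2% of the FPKM in the same order of libraries, so a shift in them moves all other values.

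From these values log2((overexpression + 1)/(wild type + 1)) was computed within each line, with a pseudocount of 1 FPKM. This scale understates the change of low genes. Genes entered with at least 1 FPKM in at least 1 library of the line. With 1 library per group no p-value can be given within a line, and a gene was called higher or lower by size alone, at a log2 ratio of at least 1 or at most -1 (a 2-fold rule). Counts shared by the 2 lines were set beside the number that independent lists would share. One test used the 2 lines as replicates: limma 3.58.1 in R 4.3.3 tested the mean of the 2 within-line log2 ratios against 0, with 1 residual degree of freedom, variance moderated with a trend on the mean level, and Benjamini-Hochberg adjustment at 0.05. It asks whether a gene moved alike in both lines.

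For gene groups, 29 lists covering RNA decay, ribosomes, differentiation, cell cycle, stress, signalling, metabolism, immunity and line identity were fixed before the data were examined, as were the size rule, the filter, the alternatives planned and the rule for naming genes. A list's median log2 ratio in a line was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and was called when it lay outside the central 95%. Lists with fewer than 5 measured members were not placed. About 5% of lists of unrelated genes would be called by chance, and more where members move together, so this is not the number expected between 2 unchanged cultures. The 4 libraries also have a wild-type comparison between the lines, made with the same size rule on values the authors scaled in separate tables.

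The rule for naming took ZCCHC7, the 12 largest rises and 12 largest falls per line, the 12 and 12 genes moving furthest in the same direction in both lines, the 2 highest and 2 lowest members of each list per line, and the 10 highest ratios each way between the wild-type libraries. Clone-based names, small RNA genes and pseudogenes were left out of these ranks. A gene that the rule names between the wild-type libraries is not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Exon overlap with another measured gene, on either strand, was recorded for each gene, because reads in shared exons can be given to either gene.

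Alternatives planned were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, ratios centred on their median, scaling by a trimmed mean of log ratios (TMM, trimming 30% of ratios and 5% of levels), rescaling without mitochondrially encoded genes and the 20 highest genes, the authors' deposited log2 fold change, 1.5-fold and 4-fold rules, limma without the trend, a 1-sample test without moderation, and random lists not matched on expression. After seeing the data, the removal of overlapping genes, pseudogenes and small RNA genes and the removal of median trends with GC content and transcript length were added. The limma step was tested on simulated ratios for 9703 genes with 200 changed: it recovered 77.5% of genes changed by a log2 of 1 and 100% of those changed by a log2 of 2 or 3, and 14 of its 198 calls were unchanged genes. The simulated noise was normal and independent between the lines, whereas the measured ratios of the lines had a Pearson's r of -0.134. These rates therefore need not hold for the measured data, where genes past the 2-fold rule in both lines, such as HACD3, went uncalled. The list step called 8 of 200 random lists of 25 genes, and 195 of 200 when all members were shifted by 0.3, in simulations on the HT29 ratios of 11327 genes. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.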

Results

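The series measured messenger RNA in HT29 and RKO, established human colorectal cancer lines, with and without overexpression of ZCCHC7. HT29 is an epithelial colon adenocarcinoma line and RKO is a poorly differentiated colon carcinoma line. ZCCHC7 is a zinc-knuckle protein of the nuclear complex that hands RNAs to the RNA exosome for decay. There were 4 groups with 1 library each, so no value below has a replicate error, and "rose" or "fell" means a change past the 2-fold size rule in these libraries. The number of genes at 1 FPKM or more was 10700 in HT29 wild type, 10898 in HT29 overexpression, 11001 in RKO wild type and 10358 in RKO overexpression.

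The first question was whether the overexpressed gene itself was higher. ZCCHC7 (ENSG00000147905, on the plus strand of chromosome 9 from 37120539 to 37358149 in GRCh38, GENCODE release 29, protein-coding) rose in HT29 from 2.84 to 8.08 FPKM, 2.85-fold, with a log2 ratio of 1.24 that was 0.74, short of the 2-fold rule, with a pseudocount of 5. In RKO it stood at 5.40 FPKM in wild type and 8.55 FPKM with overexpression, 1.58-fold, with a log2 ratio of 0.58, which did not pass the 2-fold rule. Among genes of like level, 1.76% of 567 in HT29 and 13.98% of 565 in RKO had a ratio at least as large in either direction. It ranked 137 among the rises in HT29 and 552 in RKO. Whether reads from the overexpression construct were counted under this gene is not given in the sources used here, so these ratios need not measure the whole overexpression. The authors' deposited table gives ZCCHC7 a p of 0.0285 in HT29 and 0.202 in RKO, with a q of 1 in both.

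**Figure D1:**
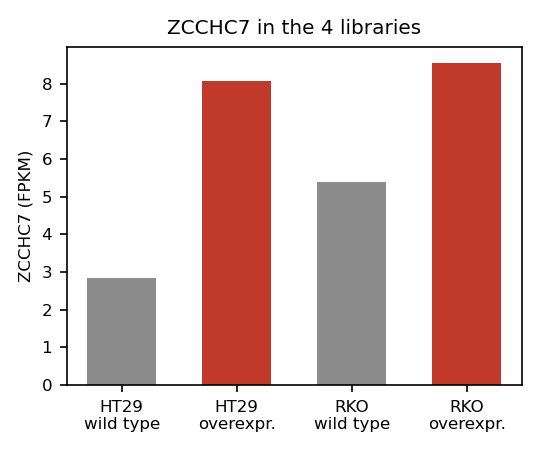
ZCCHC7 level in FPKM (vertical axis) in the 4 libraries (horizontal axis, 1 bar per library; grey, wild type; red, overexpression). The bars stand at 2.84 and 8.08 in HT29 and at 5.40 and 8.55 in RKO.

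In HT29, the comparison of the overexpression library with wild type shows a lower interferon programme, a higher median of unfolded protein response and ATF4 targets, higher differentiation genes, and lower cytosolic heat shock genes. Of 37 measured type I interferon response genes, 19 fell and none rose, with a list median log2 ratio of -1.0004; with a pseudocount of 5, 7 fell and the median was -0.55. The antiviral genes MX2 (5.22 to 0.464 FPKM, log2 ratio -2.09), OAS2 (25.1 to 7.11, -1.69), MX1 (17.8 to 4.93, -1.67) and the ubiquitin-like modifier ISG15 (345 to 109, -1.65) fell. STAT2 (2.30 to 2.89, 0.24) and UBA7 (1.26 to 0.991, -0.18) were the highest members. UBE2L6, which conjugates ISG15, fell from 23.1 to 3.03 FPKM (-2.58). IFITM1 stood at 116 and 21.5 FPKM (-2.38), but shares exons with IFITM2.

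Of 31 measured unfolded protein response and ATF4 targets in HT29, 9 rose and none fell, with a median of 0.26. Across the list 19 ratios were positive and 12 negative, so its members did not move alike. DDIT4, an inhibitor of mTORC1, rose from 7.69 to 80.2 FPKM (3.22), the glutathione-degrading enzyme CHAC1 from 1.23 to 18.1 (3.09), the pseudokinase TRIB3 from 10.2 to 69.0 (2.65) and SESN2 from 2.30 to 17.8 (2.51). The endoplasmic reticulum proteins MANF (43.3 to 24.7, -0.78) and SDF2L1 (26.3 to 16.1, -0.67) were the lowest members. Of 18 intestinal differentiation genes 5 rose and none fell (median 0.60), among them REG4 (1.13 to 13.6 FPKM, 2.78) and TFF1 (2.60 to 22.4, 2.70), while KRT20 (225 to 156, -0.52) was the lowest. The markers of HT29 identity, 11 of which are also in the differentiation list, had a median of 0.46, with 3 of 18 rising.

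Further lists lay outside the random lists in HT29. Below them were antigen presentation (median -0.47, 3 of 16 fell, among them PSMB9 from 2.84 to 0.533 FPKM, which shares exons with PSMB8), cytosolic heat shock (-0.36, 1 of 17 fell, HSPA1A from 249 to 120) and ribosome biogenesis (-0.36, none of 40 past the rule, lowest RRP9 from 82.1 to 43.7, -0.90). The mesenchymal genes (-0.32, none of 8 past the rule), replication-dependent histones (-0.27, none of 9), cytosolic ribosomal proteins (-0.15, 1 of 76 fell, RPL29 from 417 to 172) and snoRNA host genes (-0.14, 2 of 24 rose and 1 fell) also lay below. G2/M genes lay above (0.31, none of 29 past the rule, highest CDC25C from 3.995 to 7.00, 0.68). In all, 12 of 27 lists lay outside, against 1.35 for lists of unrelated genes, a number too low for lists whose members move together or are shared. The snoRNA host and histone calls ended without the filter and once the trends with GC content and length were removed, and the snoRNA host call also ended with a pseudocount of 5.

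The lists inside the random range in HT29 were led by the p53 targets (median 0.19), of which 4 of 21 rose, SESN2 included, with GDF15 from 34.7 to 99.2 FPKM (1.49) and BBC3 from 0.856 to 3.66 (1.33). Of 24 ERK immediate-early and feedback genes (0.10) 4 rose, among them the EGFR ligands HBEGF (3.30 to 12.5, 1.65) and AREG (47.2 to 97.98, 1.04). Also inside were autophagy and lysosome (0.14), cholesterol biosynthesis (0.12), epithelial junctions and keratins (0.09), hypoxia and glycolysis (0.07), mitochondrially encoded mRNAs (0.07), oxidative phosphorylation (0.06), NF-kB and TNF response (0.00, with LCN2 from 378 to 119 FPKM, -1.66), apoptosis regulators (0.00), markers of RKO identity (-0.05), TRAMP, NEXT and PAXT partners (-0.11), RNA exosome (-0.12), S phase (-0.12) and Wnt targets (-0.17). Metallothioneins (4 measured) and T cell, macrophage and fibroblast markers (3 measured) were too few to place. No member of the 16 TRAMP, NEXT and PAXT partners or of the 14 exosome genes passed the rule.

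In total 256 of 11327 genes rose and 200 fell in HT29. Beyond the lists, the growth factor MDK fell from 55.6 to 7.17 FPKM (-2.79), the trypsinogens PRSS2 (21.8 to 2.80, -2.58) and PRSS1 (13.9 to 2.44, -2.11) fell, as did the Golgi protein TGOLN2 (29.1 to 4.24, -2.52), the immune ligand CD276 (21.5 to 4.23, -2.10), PXDC1 (21.5 to 3.89, -2.20) and the endosomal GTPase RAB5B (11.4 to 1.71, -2.19). Of these, PXDC1 and RAB5B each overlap a clone-named gene. RAB43 rose from 0.0671 to 5.92 (2.70) and CHP1 from 4.01 to 28.6 (2.56). Several of the largest ratios are uncertain because exons are shared. MATR3 stood at 1.06 and 25.2 FPKM under 1 identifier and at 10.3 and 1.499 under the other. CCL15 stood at 4.91 and 38.2 while the overlapping CCL15-CCL14 stood at 17.9 and 3.09. ARPIN-AP3S2 (12.6 to 0.0180), ABHD14A-ACY1 (0.217 to 5.97) and UPK3BL1 (0.514 to 13.2) overlap their neighbours likewise. With 1 library per group these differences have no replicate check. Of the 7512 genes left without overlapping genes, pseudogenes and small RNA genes, 166 rose and 94 fell. That was 3.46% past the rule, against 4.03% of all 11327 genes. Among protein-coding genes in HT29, log2 ratios rose with transcript length (Spearman's rho 0.169). Their median was -0.06 for the shortest transcripts and 0.11 for the longest, grouped as for RKO below. With GC content rho was 0.0121.

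**Figure D2:**
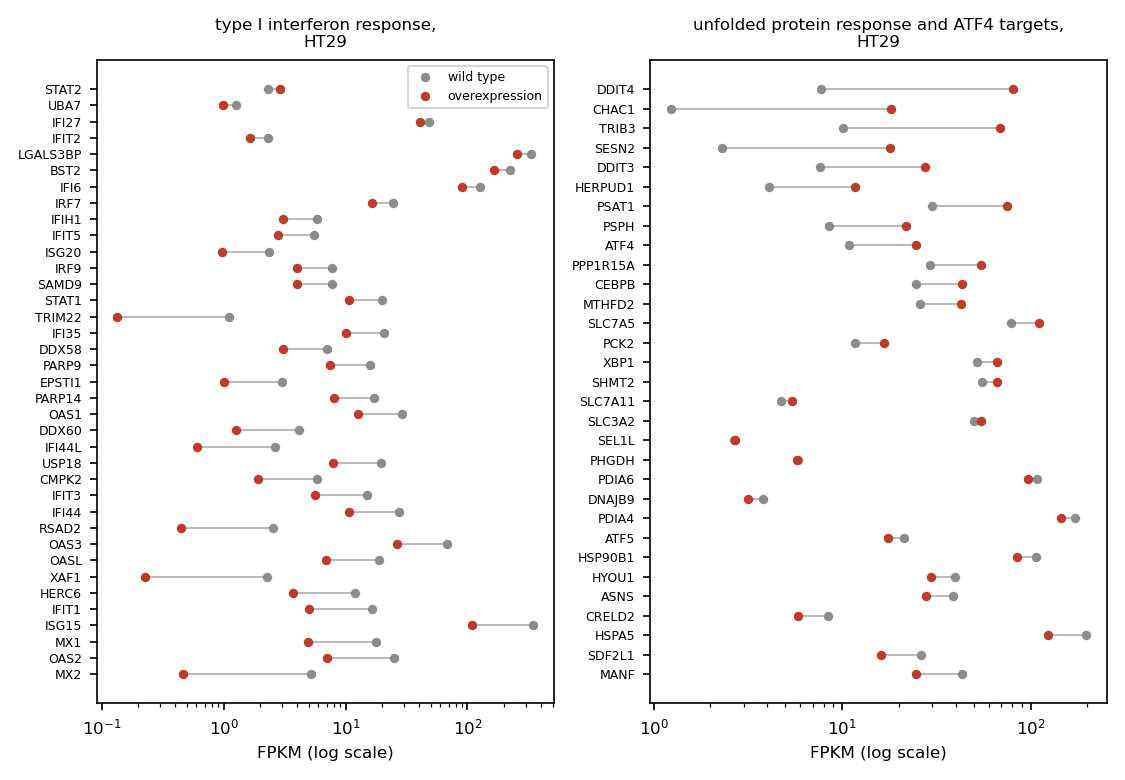
Levels in FPKM (horizontal axis, log scale) of the measured members of 2 lists in HT29 (vertical axis, 1 gene per line, ordered by log2 ratio; grey, wild type; red, overexpression). In the interferon list 36 of 37 genes lie lower with overexpression; in the other list DDIT4, CHAC1, TRIB3 and SESN2 move furthest up.

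In RKO, the ERK immediate-early and feedback list, the p53 target list and the mesenchymal list had lower medians in the overexpression library, and metallothioneins were higher. Of 23 ERK immediate-early and feedback genes 5 fell and none rose (median -0.43): the ERK phosphatase DUSP6 (59.2 to 20.7 FPKM, -1.47, which overlaps a non-coding gene), AREG (2.05 to 0.185, -1.36), the feedback inhibitor SPRY1 (1.86 to 0.162, -1.30), HBEGF (11.6 to 4.70, -1.14) and EGR3 (3.49 to 1.05, -1.13). Of 23 p53 targets 4 fell and none rose (-0.46), among them the death receptor TNFRSF10B (74.3 to 26.8, -1.44, overlapping RHOBTB2), TP53INP1 (2.63 to 0.678, -1.11) and ZMAT3 (1.504 to 0.158, -1.11), while SESN2 stood at 109 and 107 FPKM (-0.03). Of 12 mesenchymal genes 4 fell (-0.57), with the matricellular genes CCN2 (6.02 to 0.136, -2.63) and TNC (5.53 to 0.127, -2.54) lowest and CCN1 (77.3 to 125, 0.69) highest. Of 5 metallothioneins, metal-binding proteins, 3 rose (1.04): MT1E (168 to 456, 1.44), MT2A (1021 to 2585, 1.34) and MT1X (37.1 to 77.2, 1.04).

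The markers of RKO identity, which share VIM and ZEB1 with the mesenchymal list, had the lowest median in RKO (-0.73, 3 of 6 fell). Between the wild-type libraries 4 of 10 measured members of this list were higher in RKO and 4 in HT29. Its fall therefore does not show a loss of RKO identity, and AXL, which was higher in RKO, did not move (0.02). Also below the random lists were apoptosis regulators (-0.39, 4 genes shared with the p53 list, 2 of 21 fell, TNFRSF10A and the shared TNFRSF10B), antigen presentation (-0.31, 1 of 14 fell, HLA-B), hypoxia and glycolysis (-0.27, none of 28 past the rule, lowest HK2 from 31.1 to 17.9), unfolded protein response and ATF4 targets (-0.24, 1 of 31 fell, XBP1 from 55.1 to 22.1, -1.28) and mitochondrially encoded mRNAs (-0.11, none of 13 past the rule). Above the random lists were epithelial junctions and keratins (0.21, 1 of 9 rose, KRT18), S phase genes (0.19, 3 of 30 rose), RNA exosome (0.12, 1 of 14 rose) and replication-dependent histones (0.11, 2 of 23 rose, H4C12 from 11.5 to 34.8 FPKM and H2BC9 from 3.29 to 7.61). The S phase genes that rose included the replicative helicase subunits MCM5 (12.9 to 31.6, 1.23) and MCM2 (29.3 to 64.1, 1.10). The exosome subunit EXOSC6 rose from 4.06 to 12.2 FPKM (1.38). In all, 14 of 26 lists lay outside, against 1.3 for lists of unrelated genes, to which the same limit applies. Under TMM scaling the medians were -0.03 for unfolded protein response and ATF4 targets, -0.08 for hypoxia and glycolysis, -0.11 for antigen presentation, -0.24 for ERK genes, -0.24 for apoptosis regulators, -0.27 for p53 targets, 0.26 for histones, 0.32 for exosome, 0.39 for S phase and 0.39 for junctions and keratins, all still called, and mitochondrially encoded mRNAs turned positive (0.10) but stayed below the random lists. Calls ended without the filter (mesenchymal genes, RKO identity, junctions and keratins, exosome, histones), with a filter at 5 FPKM (mesenchymal genes, hypoxia, apoptosis, exosome, histones), without overlapping genes, pseudogenes and small RNA genes (antigen presentation, apoptosis, junctions and keratins, exosome), against unmatched random lists (unfolded protein response and ATF4 targets, hypoxia, mitochondrially encoded mRNAs, antigen presentation), and after the trends with GC content and length were removed (exosome, histones).

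Inside the random range in RKO were cytosolic ribosomal proteins (median 0.17), cytosolic heat shock (0.12), oxidative phosphorylation (0.12), ribosome biogenesis (0.07), G2/M (-0.01), snoRNA host genes (-0.05), cholesterol biosynthesis (-0.11), autophagy and lysosome (-0.12), TRAMP, NEXT and PAXT partners (-0.14), Wnt targets (-0.16), type I interferon response (-0.23) and NF-kB and TNF response (-0.24). Within the Wnt list MYC rose from 4.01 to 12.3 FPKM (1.41) and CD44 fell from 12.2 to 5.21 (-1.09). Of 17 measured interferon genes 1 fell, IFI27 from 4.28 to 0.448 FPKM (-1.87). Intestinal differentiation, markers of HT29 identity (2 measured members each) and T cell, macrophage and fibroblast markers (1 measured) were too few to place.

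In total 157 of 11302 genes rose and 315 fell in RKO, with a median log2 ratio of -0.13 over all genes. That split depended on the scaling: with the ratios centred on their median, 218 rose and 210 fell, and with TMM scaling, which put the median at 0.04, 267 rose and 227 fell. Among single genes, TGOLN2 fell from 26.0 to 1.76 FPKM (-3.29), the Hippo pathway kinase STK4 from 18.03 to 1.68 (-2.83), the G protein regulator RGS4 from 42.3 to 5.44 (-2.75), CHP1 from 35.7 to 4.62 (-2.71), the ubiquitin ligase RNF185 from 14.3 to 1.40 (-2.67), the histamine receptor HRH1 from 4.67 to 0.0231 (-2.47) and HSD3B7 from 24.7 to 3.90 (-2.39). RAB5B rose from 2.18 to 15.04 (2.33), COLEC10 from 0.0617 to 3.85 (2.19) and TOMM6, a subunit of the mitochondrial import pore, from 6.19 to 110 (3.94). RAB5B, HSD3B7 and TOMM6 overlap non-coding genes. The read-through genes at the ends of the ranking share exons with their parts: BLOC1S5-TXNDC5 went from 40.9 FPKM to a value listed at 0 while TXNDC5 went from 24.6 to 87.9, and PTGES3L-AARSD1 went from 12.6 to 0.0956 while AARSD1 went from 2.33 to 12.5. FMC1-LUC7L2, TM4SF19-TCTEX1D2, SENP3-EIF4A1 and BIVM-ERCC5 (higher) and RPL17-C18orf32 (lower) are uncertain for the same reason. SCAMP5 rose from 3.504 to 17.7 (2.06) and the long non-coding LINC02085 from 0.380 to 4.62 (2.03), and both overlap another gene. Median log2 ratios in RKO went from -0.30 in the fifth of protein-coding genes with the lowest GC content to 0.02 in the fifth with the highest, and from 0.03 in the fifth with the shortest transcripts to -0.27 in the fifth with the longest.

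**Figure D3:**
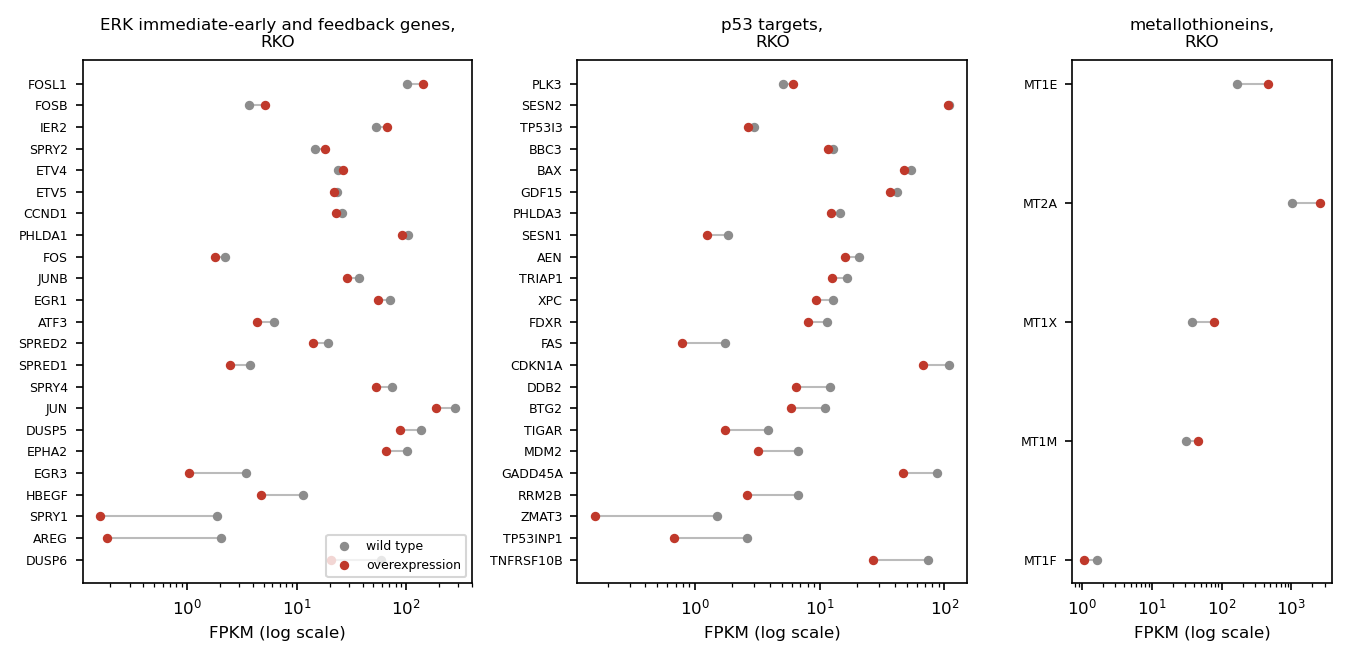
Levels in FPKM (horizontal axis, log scale) of the measured members of 3 lists in RKO (vertical axis, 1 gene per line, ordered by log2 ratio; grey, wild type; red, overexpression). In the ERK list 18 of 23 genes and in the p53 list 22 of 23 genes lie lower with overexpression; 4 of 5 metallothioneins lie higher.

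**Figure D4:**
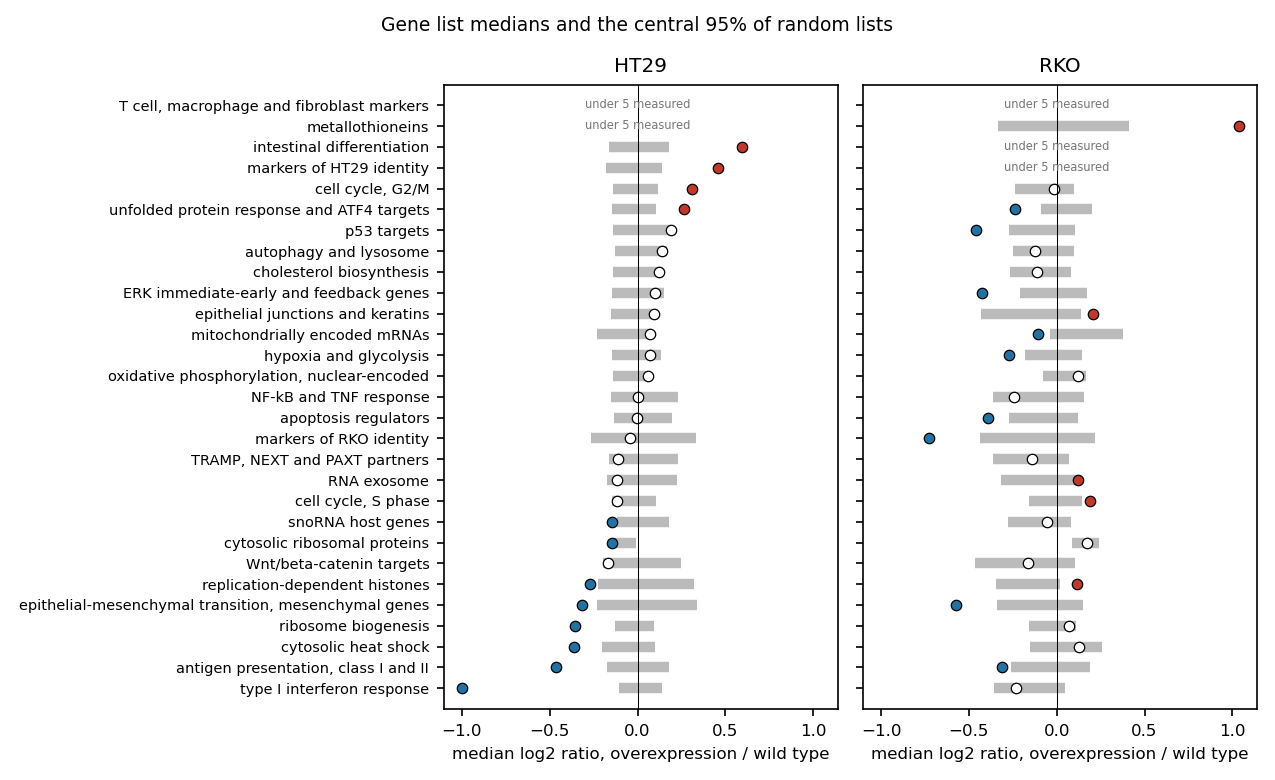
Median log2 ratio of overexpression over wild type (horizontal axis) for each gene list (vertical axis) in HT29 (left) and RKO (right); grey bars give the central 95% of 10000 random lists, and points are red above it, blue below it and white inside it. The interferon list stands lowest in HT29 at -1.0004 and metallothioneins highest in RKO at 1.04.

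The next question was whether the same genes moved in both lines. TGOLN2 fell in both, and HLA-B fell from 21.4 to 3.84 FPKM in HT29 (-2.21) and from 67.5 to 18.5 in RKO (-1.82), with exons shared with HLA-C. Lower in both were also the fatty acid elongation enzyme HACD3 (-1.45 and -1.52), CRCP (-1.39 and -1.32), FN3KRP (-1.80 and -1.23), the transcription factor MAFK (-1.19 and -1.71, overlapping TMEM184A), LAMP3 (-1.61 and -1.07), the retinoic acid binding protein CRABP2 (-1.07 and -1.92), FAM220A (-1.04 and -1.46) and FAM219B (-1.13 and -1.01, overlapping MPI). The epithelial membrane protein EMP1 rose in both (1.74 and 1.98), as did the sialidase NEU3 (2.37 and 1.24), TRIM56 (1.09 and 1.29), and UPK3BL1, ATP6V1G2-DDX39B and SENP3-EIF4A1, which share exons with other genes. ZBED6 rose (1.90 and 1.39) and ZC3H11A, within which it lies, fell (-1.14 and -1.53), so the share of reads given to each is uncertain. UPK3BL2 (overlapping POLR2J3), UHMK1, RHNO1 (overlapping TULP3), U2AF1, SLC25A22 and CXCL8 moved the same way in both lines but passed the rule in 1 line.

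Of 9703 genes measured in both lines, 24 passed the rule in the same direction, against 4.97 for independent lists, and 40 passed it in opposite directions, against 5.30. These expected numbers treat every gene as equally likely to pass the rule, but overlapping genes passed it more often in both lines. An excess in both directions therefore does not by itself show a shared or an opposed response. With overlapping genes, pseudogenes and small RNA genes left out, 10 passed in the same direction, against 2.21, and 26 in opposite directions, against 2.85. These counts argue against overlap as the whole cause of the excess. Across genes, which are not independent replicates, Pearson's r of the 2 sets of log2 ratios was -0.134 and Spearman's rho was -0.132. Without MIR1244-1, a short RNA gene with log2 ratios of -9.14 in HT29 and 8.25 in RKO that was singled out after its values were seen, r was -0.0984 and rho -0.132. With a pseudocount of 5 the counts were 8 in the same direction, against 0.433 for independent lists, and 6 in opposite directions, against 0.430.

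**Figure D5:**
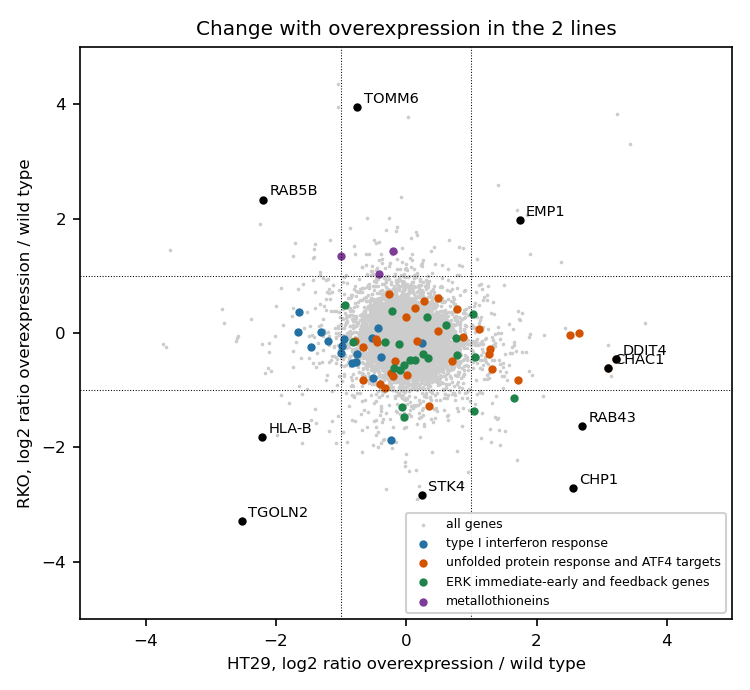
Log2 ratio of overexpression over wild type in HT29 (horizontal axis) and RKO (vertical axis) for 9703 genes, with 4 lists in colour, 10 genes named and dotted lines at the 2-fold rule; 2 genes lie outside the axes. TGOLN2 and HLA-B lie low in both lines, EMP1 lies high in both, and CHP1, RAB43 and RAB5B lie on opposite sides.

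With the 2 lines as replicates, limma called 6 of 9703 genes at an adjusted p under 0.05, 4 higher and 2 lower. TGOLN2 was lower by a mean log2 ratio of -2.91 (SE 0.271, limma adjusted p = 0.00368) and HLA-B by -2.01 (SE 0.247, adjusted p = 0.0302). EMP1 was higher by 1.86 (SE 0.246, adjusted p = 0.0387), UPK3BL1 by 3.53 (SE 0.269, adjusted p = 0.00142) and ATP6V1G2-DDX39B by 1.92 (SE 0.251, adjusted p = 0.0387). The sixth, the clone-named AC138811 (3.37, SE 0.271, adjusted p = 0.00142), was chosen after its values were seen. Of these 6, TGOLN2 and EMP1 have no recorded overlap with another measured gene. Each gene was lower or higher in 2 of 2 lines, and the unadjusted p was under 0.05 for 327 genes, fewer than the 485 given by chance. Over the highest and lowest of the other settings, the limma adjusted p of TGOLN2 ran from 4.10e-06 to 0.999 that of EMP1 from 0.00201 to 0.999, that of HLA-B from 0.0105 to 0.999 and that of ATP6V1G2-DDX39B from 0.0128 to 0.999. Those of UPK3BL1 and AC138811 both ran from 0.000276 to 0.999. HLA-B, EMP1 and ATP6V1G2-DDX39B were not called with median-centred ratios, with TMM scaling or after trend removal, and TGOLN2 was not called after trend removal (limma adjusted p = 0.0949). EMP1 and ATP6V1G2-DDX39B were also not called with the 5 FPKM filter or without mitochondrially encoded genes and the 20 highest genes. AC138811 was not called with the 5 FPKM filter, and none of the 6 was called without the filter. Adjusted over the list alone, limma called HLA-B in antigen presentation (adjusted p = 0.000174) and CXCL8 in the NF-kB and TNF response (adjusted p = 0.0258), and no member of the other 27 lists. Over all genes tested CXCL8 did not pass (limma adjusted p = 0.632). It stood at 4.72 and 0.987 FPKM in HT29, and at 1.02 and 0.0237 FPKM in RKO, barely past the filter. Adjusting within each list leaves the number of lists uncorrected.

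The authors' deposited table marks 439 genes in HT29 as significant, 259 higher and 180 lower, and 428 in RKO, 152 higher and 276 lower. At a q under 0.05 there are 54 genes in HT29 (29 higher) and 42 in RKO (13 higher). Of the genes past the 2-fold rule, 264 of 456 in HT29 and 266 of 472 in RKO are among those the authors' deposited table marks. Among the genes named above, TGOLN2, ZBED6, CHP1 and RAB5B have a q under 0.05 in both lines there, and DDIT4, CHAC1, REG4, TFF1, TRIB3, SESN2, MDK, PRSS2, UBE2L6, NEU3, LAMP3, MATR3, CCL15 and ABHD14A-ACY1 in HT29 alone. In RKO alone they are TNC, TOMM6, STK4, RGS4, RNF185, SENP3-EIF4A1 and BIVM-ERCC5.

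The series' design text also sets the 2 cell types side by side. Between the wild-type libraries, the highest ratios towards HT29 were those of S100P (1386 FPKM), LYZ (602), KLK6 (506), KRT19 (501), LCN2 (378), LGALS4 (303), GPX2 (281), TM4SF4 (268), KRT20 (225) and SNCG (210), each at 0.169 FPKM or less in RKO. The highest towards RKO included G0S2 (697 FPKM), LGALS1 (447), STC1 (284), AXL (162), CLEC11A (142), MAP1LC3C (122), LCP1 (109), BCL2A1 (108) and BEX3 (86.8), each at 4.05 FPKM or less in HT29. Of 18 measured markers of HT29 identity 17 were higher in HT29 and none in RKO. Of 10 measured markers of RKO identity 4 were higher in RKO (VIM, ZEB1, AXL and GLIPR1) and 4 were higher in HT29 (MSN, BDNF, MAGEA3 and MAGEA6). Of 21 T cell, macrophage and fibroblast markers 18 were under 1 FPKM in all 4 libraries, the others being LYZ, CD14 and CD68. In total 1786 of 12431 genes were higher in HT29 and 2102 in RKO, a balance that turned with TMM scaling (2005 and 1929). Across 12926 genes, Pearson's r of log2 levels was 0.969 between the libraries of each line and 0.743 between the wild-type libraries of the 2 lines. The tables of the 2 lines were normalised separately.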

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

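The rank test of the GC and length trend under the first pattern and the test of library scaling under the second were chosen only after the result was seen.

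These genes and lists moved one way in HT29 and the other way in RKO, and with 1 library per group the difference was not tested. CHP1, a calcineurin-like calcium sensor, had log2 ratios of 2.56 in HT29 and -2.71 in RKO, a difference of 5.27. RAB5B, whose exons overlap a non-coding gene, stood at -2.19 and 2.33, a difference of -4.53. RAB43 stood at 2.70 and -1.63, a difference of 4.32. The EGFR ligands HBEGF (1.65 and -1.14, difference 2.79) and AREG (1.04 and -1.36, difference 2.40) both rose in HT29 and fell in RKO. MT2A fell in HT29, where it was barely past the rule, and rose in RKO (-1.0003 and 1.34, difference -2.34). The unfolded protein response and ATF4 list had medians of 0.26 and -0.24, a difference of 0.501, but the RKO median was -0.03 with TMM scaling and its call ended against unmatched random lists. Replication-dependent histones had medians of -0.27 over 9 genes in HT29 and 0.11 over 23 in RKO, a difference of -0.387. These medians cover different sets of genes. The list lay inside the random lists in both lines without the filter. Both calls also ended once the trends with GC content and length were removed.

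The first pattern is the opposite movement of the lines: Spearman's rho across genes, which are not independent replicates, was -0.132. The counts past the rule do not carry it alone. Both 40 opposite (against 5.30 for independent lists) and 24 same-direction genes (against 4.97) were in excess. A pseudocount of 5 gave 6 (against 0.430) and 8 (against 0.433). The lines had opposite trends with transcript length: Spearman's rho of the log2 ratio with length was 0.169 in HT29 and -0.280 in RKO. With GC content rho was 0.0121 in HT29 and 0.331 in RKO. Removing the trends with GC content and length left Pearson's r at -0.115 (95% interval -0.209 to -0.0484), which did not decide, so a rank test was added: rho was -0.106 (-0.127 to -0.0849, 9684 genes). That argues against the trends as the whole cause only, since part of rho went with them and Pearson's r without MIR1244-1 was -0.0763; without overlapping genes, pseudogenes and small RNA genes r was -0.121 (-0.157 to -0.0810, 6401 genes), and among genes at 5 FPKM or more in all libraries it was -0.123 (-0.160 to -0.0818, 4114 genes), which argues against both as the whole cause. A line-specific response to ZCCHC7, its unequal level (2.85-fold in HT29, 1.58-fold in RKO) and differences between cultures stay open, untested, with 1 library per group.

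The second pattern is the lower interferon response in HT29, with a list median of -1.0004. After the trends with GC content and length were removed the median was -1.08, against -0.0962 to 0.142 for random lists, which argues against them as the cause. RKO-specific genes stood at a median of 0% of their RKO level in the HT29 overexpression library, and at most at 0.0194% over 7 genes, which argues against admixed RKO cells. The median log2 ratio of all genes was 0.0246, which argues against library scaling. ZCCHC7 overexpression and a difference between the 2 cultures, such as density or clone, stay open, untested.

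The third pattern is the excess of overlapping genes among those past the 2-fold rule, 32.5% against 26.6% of all genes in HT29 and 32.0% against 27.1% in RKO. If reads were divided differently between overlapping genes, partners would move in opposite ways. Of 90 partners that moved by a like amount 53.3% did so (43.1% to 63.3%), below the 75% set for this cause, but with an upper bound above the 60% set against it; 14 pairs were counted from both sides, and with each pair once it was 51.3% of 76 (40.3% to 62.2%), which also decides nothing. A shift of reads between partners and a change in expression therefore cannot be told apart for these genes.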

How the results depend on the processing

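The removal of overlapping genes, pseudogenes and small RNA genes and the removal of GC and length trends were chosen only after the result was seen. No ratio of a named gene past the 2-fold rule changed sign, which these settings could hardly have brought about. Smaller ratios were not counted, and that of SESN2 in RKO (-0.03) turned positive once the RKO median of -0.13 was taken off. Of the values of named genes over the settings, 117 moved, with a pseudocount of 0.1 (45) or 5 (72), and 3744 did not. Of the list calls, 10 of 12 in HT29 and 4 of 14 in RKO (S phase, p53, ERK and metallothioneins) held in every setting that placed them. HT29 mesenchymal genes and RKO metallothioneins had too few members to place with the 5 FPKM filter. Counts are given as HT29 higher and lower, RKO higher and lower, then same and opposite direction in both lines; where neither fewer genes tested nor another size rule shows it, the cause was not tested. Pseudocount 0.1: 534, 416, 285, 754, 52 and 96. Pseudocount 5: 63, 61, 48, 68, 8 and 6, with 740 genes higher in HT29 and 739 in RKO between wild types. A filter at 5 FPKM, with fewer genes tested: 140, 123, 98, 183, 14 and 19, with 1133 and 1200 between wild types and 7 RKO lists called. Without overlapping genes, pseudogenes and small RNA genes, with fewer genes tested: 166, 94, 67, 196, 10 and 26, with 9 RKO lists called. The share past the rule in that setting was 3.46% in HT29 and 3.54% in RKO, against 4.03% and 4.18% of all genes. The first 4 counts were 843, 674, 541 and 1291 with a 1.5-fold rule, 28, 29, 23 and 36 with a 4-fold rule, and 582, 443, 306 and 847 with the authors' deposited log2 fold change. TMM scaling gave 267 genes higher in RKO. limma across lines called 3 genes with the 5 FPKM filter, 3 with median-centred ratios, 3 with TMM scaling, 2 after the GC and length trends were removed and 0 without the filter, and a test without moderation called 0; the cause was not tested. Medians of called lists that changed sign were histones without the filter (0.0106 in HT29, -0.0134 in RKO), RKO histones after trend removal (-0.13), and RKO junctions and keratins without the filter (-0.00712) and without overlapping genes (-0.49), and RKO mitochondrially encoded mRNAs with median-centred ratios (0.0244) and TMM scaling (0.105), where all RKO ratios shift up together; for the others the cause was not tested. Among RKO lists not called, G2/M, snoRNA hosts, cholesterol and autophagy also turned positive under both scalings (0.119, 0.0807, 0.0236 and 0.0114 when centred). Leaving out a library in turn was not run, with 1 per group, and alternatives that need counts were not run.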

Other observations

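The scan of KEGG pathways was chosen only after the result was seen for the lists, as was the snoRNA comparison, and the test of long non-coding RNA was written before it.

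In HT29, protein export had the lowest pathway median (-0.26), though 1 of 23 genes passed the 2-fold rule, the signal peptidase subunit SPCS2, which fell from 30.7 to 14.6 FPKM (-1.03). SRPRB (25.3 to 12.2, -0.99), SEC11C (8.75 to 4.14, -0.92) and the chaperone HSPA5 (197 to 124, -0.67) did not pass it. Protein processing in the endoplasmic reticulum also lay below random lists (-0.11, 140 genes, 3 rose and 2 fell), whereas the unfolded protein response and ATF4 list lay above them. In complement and coagulation (-0.19, 20 genes) the urokinase receptor PLAUR fell from 18.02 to 7.80 FPKM (-1.11). Propanoate metabolism had a median of 0.30 with 0 of 22 genes past the rule, the largest ratios being those of the acetyl-CoA synthetases ACSS1 (3.93 to 7.87, 0.85) and ACSS2 (2.07 to 4.16, 0.75). Of 263 pathways 77 lay above and 18 below random lists, and 47 and 12 also did so after the GC and length trends were removed. Unrelated genes would give 6.58 on each side, a number too low for pathways whose members move together or are shared. ADCY6 and PLCB3, for example, were among the highest members of insulin, gastric acid and salivary secretion alike. These genes were chosen after their values were seen.

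In RKO, ECM-receptor interaction had a median of -0.62 (24 genes, 5 fell), with the integrin ITGB1 (154 to 60.3 FPKM, -1.34, overlapping a divergent transcript), the dystroglycan DAG1 (15.2 to 5.56, -1.30) and COL9A3 (7.89 to 2.79, -1.23, overlapping TCFL5). Complement and coagulation stood lowest (-0.74, 16 genes), with the thrombin receptor F2R falling from 1.69 to 0.240 FPKM (-1.12). The cytokine IL11 fell from 16.4 to 7.06 FPKM (-1.11) and the proteoglycan SDC3 from 4.37 to 1.47 (-1.12). DNA replication had a median of 0.21 (2 of 34 rose), the proteasome 0.14 (0 of 42) and the spliceosome 0.11 (1 of 126), all above random lists. The KEGG ribosome set lay just above random lists (0.1701 against an upper limit of 0.1682), while the cytosolic ribosomal protein list lay inside them; the mitochondrial subunit MRPL30 rose from 4.82 to 17.5 FPKM (1.67). Of 257 pathways 12 lay above and 34 below, and 9 and 27 also did so after trend removal. Unrelated genes would give 6.43 on each side, to which the same limit of shared members applies. These genes too were chosen after their values were seen.

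A hypothesis was that more ZCCHC7 would lower long non-coding RNAs, many of which the exosome degrades. It needed their median to lie below expression-matched random lists in both lines. The median was 0.127 in HT29 (511 genes, random lists 0.0213 to 0.0994) and -0.0314 in RKO (620 genes, random lists -0.244 to -0.180), above the random lists in both, so the prediction failed. In RKO this place was not particular to long non-coding RNA. Pseudogenes there (0.00243, random lists -0.183 to -0.121) also lay above, whereas in HT29 they lay below (-0.0926). The random lists were matched on expression alone, not on transcript length or GC content, with which RKO ratios trended. In RKO ZCCHC7 was only 1.58-fold higher and short of the 2-fold rule. The genes tested had at least 1 FPKM in poly(A)-selected libraries. RNAs kept low by decay or without a tail could not enter, so the hypothesis is not decided for them. The snoRNA genes, looked at without a prediction, had a median of -0.242 in HT29, below random lists, and -0.106 in RKO, above them; in each line 4 of 65 rose and 10 fell. The libraries were poly(A)-selected, so RNAs without a tail were selected against.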
